A study of Danio rerio with 16 samples.

How the data were processed

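Gene expression was measured in whole zebrafish embryos on 16 single-colour (Cy3) oligonucleotide arrays of Agilent design 019161. Per the labels, embryos under 2 hours old were exposed for 48 hours, 24 embryos were pooled per replicate, and 500 ng of total RNA were labelled. The replicates are thus separate pools of 24 embryos, and each array holds 1 pool. There were 4 groups of 4 replicates, lettered A to D: a water control, a solvent control (acetone, the solvent of genistein), genistein at 2.2 mg/l (EC10) and genistein at 2.4 mg/l (EC20). What effect the percentages of the EC values refer to is not given in the sources used here. Each replicate letter stood for 1 slide, which carried 1 array of each of the 4 groups.

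The deposited values are of the unit intensity. Per the file headers, the authors extracted each scan with Agilent Feature Extraction 9.5.1.1, which subtracted a background surface, removed a multiplicative trend and gave dim spots a surrogate value. No scaling between arrays had been applied. The deposited series table holds the same intensity rounded to 3 significant digits. Its values differed from the array files by at most 0.497%. The number of arrays limits the precision of every comparison.

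Control spots and spots marked as non-uniform or as population outliers were left out. Spots of 1 probe were averaged on the log2 scale, and the 75th percentile of each array was subtracted. A probe was kept when it was well above background on at least 3 of the 4 arrays of at least 1 group. Of 43603 probes, 28132 passed. A gene with several probes was represented by the probe with the highest mean signal, which left 22217 genes. Gene names were taken from the reference table of zebrafish genes for 21099 probes, of which 16075 matched by transcript accession, 2624 by Entrez ID, 954 by current symbol and 1446 by an older symbol. The other 22504 probes kept the name in the files. Probe positions are those of the files, on the build danRer5.

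All 16 arrays were fitted together in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), with a mean per group, so that the 4 groups share 1 estimate of the spread. The 5 comparisons were solvent control against water control, EC10 against solvent control, EC20 against solvent control, the mean of both doses against solvent control, and EC20 against EC10. P values are 2-sided and Benjamini-Hochberg adjusted over all genes. A gene was called at an adjusted p under 0.05. Fold changes are log2 differences with their standard error (SE). Where a gene was not above background on any array of a group, its fold is given as a bound. The bound averages all arrays of the other group, so bounds at EC20 include replicate A. For the genes of the estrogen list, exact 2-sided permutation tests of the group means were also run. On simulated data with 22217 genes, the fit for EC20 against solvent control recovered 11.9% of genes changed 2-fold and 75.8% of those changed 4-fold. For EC10 the shares were 5.97% and 86.4%, and for solvent control against water control 10.4% and 74.2%. For the mean of both doses they were 31.3% and 89.4%, and for EC20 against EC10 8.96% and 87.9%. The simulated sets gave 2 to 6 false calls. In each set only 67 genes were changed 1.5-fold, 67 2-fold and 66 4-fold, and all arrays had the same spread for a gene. The real arrays differ in both respects, so these shares need not hold for the real comparisons.

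The 34 gene lists covered estrogen response, steroidogenesis and gonadal axis, thyroid axis, aryl hydrocarbon response, pregnane and phase I xenobiotic response, conjugation phase II, oxidative stress (nrf2), p53 and apoptosis, heat shock, unfolded protein and integrated stress response, cell cycle, ERK and growth factor feedback, angiogenesis and endothelium, erythroid cells, myeloid cells and inflammation, skeletal muscle, cardiac muscle, neurons, neural progenitors and glia, retina and photoreceptors, lens, liver, exocrine and endocrine pancreas, intestine and ionocytes, pigment cells, cartilage, bone and matrix, epidermis and keratin, hatching gland, sterol synthesis, fatty acid oxidation and PPAR, glycolysis and hypoxia, circadian clock, oxidative phosphorylation, and ribosomal proteins. Each was tested against the other genes with limma's cameraPR at a preset inter-gene correlation of 0.01, adjusted over the 34 lists, and again with an estimated correlation. A list's shift is its mean log2 change minus that of all genes.

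By the rule for named genes cyp19a1b is named in every comparison. The 12 largest rises and the 12 largest falls come from called genes with a gene symbol whose treated arrays all lay on 1 side of all reference arrays. Each list adds up to 4 called members with the largest change, or the 2 largest as values where a called list had no called member. Some of the genes so chosen are left out of the text. Further genes are named only where a count was small, or as list members, and these were picked after their values were seen.

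The groups, comparisons, lists, filter, scaling and rule for named genes were chosen before the data were examined, as were the other settings run: normexp background correction (offset 50), quantile or median scaling, the values of the series table, no filter or a filter over all 16 arrays, the replicate letter as a block with and without array position, other probe and variance rules, fits of the compared groups alone, the other control group, and leaving out each array in turn. After the data were seen, fits without the array of EC20 replicate A in every comparison, with array weights and with a capped local background were added. No array was left out of the values reported first.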

Results

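Whole zebrafish embryos were profiled at 48 hours after fertilization in 16 samples. There were 4 each of water control, solvent control, genistein EC10 (2.2 mg/l) and genistein EC20 (2.4 mg/l). Genistein is a soy isoflavone that binds estrogen receptors. The 75th percentile of the processed signal ran from 175 to 324 on 15 of the arrays, and 56.3% to 66.5% of their spots were well above background. The array of EC20 replicate A stood apart, with a 75th percentile of 1099, 93.1% of spots well above background and 18.6% of spots marked non-uniform. Its correlation with the other arrays, across genes, was 0.812 to 0.844, while the other 15 correlated at 0.945 to 0.992 with each other. Genes are not independent replicates, so no p is attached to these correlations. It gave a value for 18641 of the 22217 genes, and every comparison is therefore also given without it, a fit added after the data were seen.

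The comparison of solvent control with water control asked whether acetone alone changed expression. Brain aromatase (cyp19a1b), which converts androgens to estrogens in radial glia and is induced by estrogens, differed by 0.04 (SE 0.19, n = 4 per group, adjusted p = 0.953, exact 2-sided permutation p = 0.771). The list of neural progenitors and glia was the only 1 of 34 lists called, with a shift of -0.25 (adjusted p = 0.00312). That call was lost with adjusted p = 0.957 with an estimated correlation, and 0 of its 42 measured members were called by limma, over all genes or adjusted over the list alone. Its largest differences were those of glula, a glutamine synthetase of glia (-0.68, SE 0.32), and gfap, the glial filament protein (-0.57, SE 0.34). Over all genes, limma called 0 higher and 0 lower, with 1095 genes at unadjusted p under 0.05 where 1111 were expected by chance, at a median SE of 0.30. Without EC20 replicate A that SE was 0.20 and 3733 genes were at unadjusted p under 0.05. With array weights, also added after the data were seen, 2694 genes were higher and 3433 lower. The weights were estimated from these same arrays and ran from 0.0316 to 4.18, so these counts may be too high. The 0 calls of the fit on all arrays therefore do not show that acetone left expression unchanged. Of 22166 genes with values on all arrays compared, 4.95% had groups that did not overlap, where chance gives 2.86%. In the fit without that array, which enters through the shared spread, 1 gene was higher, the potassium channel kcnj1a.2 (1.74), and 2 were lower, the complement gene c1qb (-2.65) and the transcript EH552414 (-1.83), and without solvent replicate A 1 gene was higher. The glia call was lost without water replicate A (shift -0.17, adjusted p = 0.0696), which left 0 lists called, and 2 lists were called without water replicate C.

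The comparison of EC10 with solvent control asked what 2.2 mg/l genistein changed. Genes that respond to estrogens rose: cyp19a1b 6.72-fold (log2 2.75, SE 0.19, n = 4 per group, adjusted p = 5.37e-06) and vtg1, which encodes the egg yolk precursor vitellogenin, 4.88-fold (log2 2.29, SE 0.25, adjusted p = 0.000665). Coagulation factor XIII (f13a1a.1) rose as well (log2 3.47, SE 0.43, adjusted p = 0.00229), but was above background on only 1 of the 4 solvent arrays, so the size of its change at either dose is not well measured. The only gene that fell was g0s2, an inhibitor of fat breakdown, by 4.35-fold (log2 -2.12, SE 0.33, adjusted p = 0.0209). Each of the 4 genes moved in the same direction on all 4 slides. For cyp19a1b the 4 slides gave 2.64, 2.96, 2.98 and 2.42. On build danRer5 the probe of cyp19a1b lies on chromosome 25 at 2989477 to 2989564, that of vtg1 on chromosome 22 at 23098713 to 23098772 and that of f13a1a.1, named zgc:152982 in the files, on chromosome 24 at 1729605 to 1729664.

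Of the 7 measured genes of the estrogen list, 3 rose at EC10, 0 fell and 4 did not pass (shift 1.33, adjusted p = 1.37e-17). The call held with adjusted p = 7.51e-11 with an estimated correlation, and adjusted over the list alone 4 genes rose. The added gene was nots, a liver aspartic protease (log2 0.97), and for each of the 4 genes the exact 2-sided permutation p was 0.0286, the smallest that 4 arrays against 4 can give (0.05 after adjustment over the list's 7 genes). The estrogen receptors esr1 (-0.05) and esr2b (-0.02) and the receptor corepressor nrip1a (-0.18) did not pass. In the control groups cyp19a1b had a mean of -4.32 (SD 0.19, n = 4) in water and -4.28 (SD 0.15, n = 4) in solvent, log2 relative to the array's 75th percentile, against -1.53 (SD 0.21, n = 4) at EC10.

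**Figure D1:**
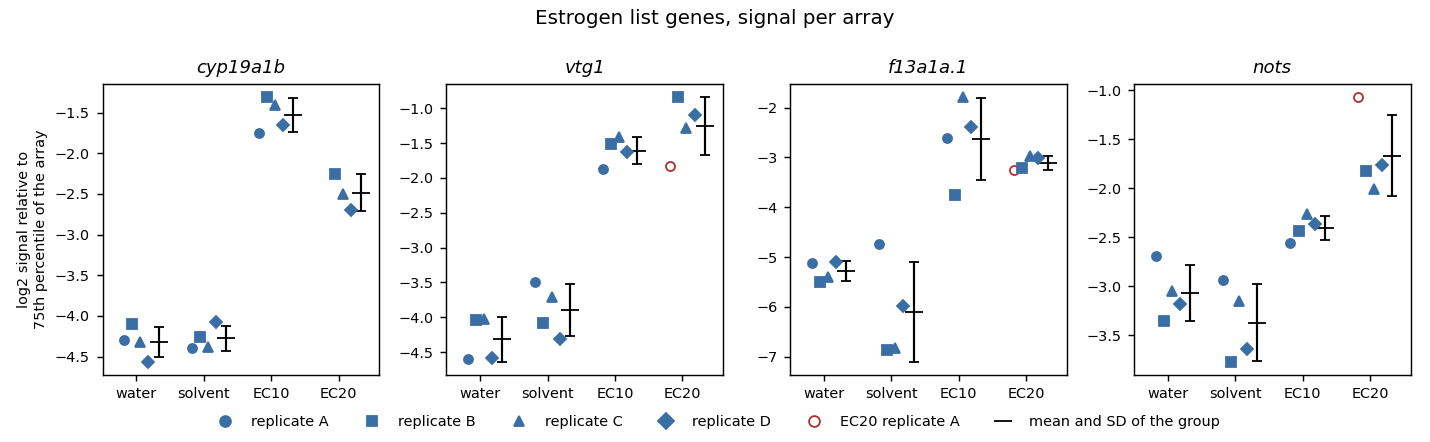
Log2 signal relative to the array's 75th percentile (vertical axis) of cyp19a1b, vtg1, f13a1a.1 and nots on each array of the 4 groups (horizontal axis); symbols are replicates, the open red circle is EC20 replicate A, and bars are the group mean and SD. Brain aromatase lay at -4.28 in solvent controls, -1.53 at EC10 and -2.48 at EC20.

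A further 7 lists were called at EC10, with 0 members called over all genes in any of them (limma) and none held with an estimated correlation. The myeloid and inflammation list rose by 0.17 (adjusted p = 0.00465, and adjusted p = 0.828 with an estimated correlation), with isg15, an interferon-stimulated ubiquitin-like protein, at 1.40 (SE 0.47). The p53 and apoptosis list rose by 0.19 (adjusted p = 0.0119), with bbc3, the pro-apoptotic Puma, at 1.70 (SE 0.35, adjusted p = 0.194) and 1 of 40 members called adjusted over the list alone. The liver list rose by 0.09 (adjusted p = 0.0419), with tdo2b, at background on all EC10 arrays, at least 1.59-fold lower and rbp2a at 0.78, while the lists of heat shock (-0.16, adjusted p = 0.0119), ERK and growth factor feedback (-0.11, adjusted p = 0.0317), unfolded protein and integrated stress response (-0.11, adjusted p = 0.0419) and circadian clock (-0.13, adjusted p = 0.046) fell. For these 6 lists adjusted p = 0.929 with an estimated correlation. Their largest members were hspa8b (-0.96) and dnajb1b (0.84), egr1 (-0.72) and npas4a (-0.63), txnipa (-0.70) and dnajb9b (-0.50), and nfil3-6 (-0.77) and roraa (-0.75). Adjusted over the list alone, 0 members of the myeloid, liver, heat shock, ERK, unfolded protein and circadian lists were called. Leaving out single arrays ended these calls too: p53 without solvent replicate D (adjusted p = 0.0599), heat shock without solvent replicate B (0.0671) or EC10 replicate D (0.0608), the liver list without solvent replicates A, C or D or EC10 replicates B or D (0.0517 to 0.344), and the ERK and unfolded protein lists without solvent replicates A or B or EC10 replicates A, C or D (0.0769 to 0.293 and 0.0573 to 0.168). The circadian call was lost without solvent replicates A, B or D or EC10 replicates A, C or D (0.0679 to 0.163). Of the 8 calls, 5 were left without EC10 replicate A, 4 without solvent replicate B and 3 without EC10 replicate D. Slide A gave -0.37 for the ERK list (others -0.037 to -0.013) and -0.010 for the p53 list (others 0.21 to 0.28).

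Over all genes, limma called 7 higher and 1 lower at EC10, with 491 genes at unadjusted p under 0.05 where 1111 were expected by chance. The median SE was 0.30, and without EC20 replicate A it was 0.20 with 1318 genes at unadjusted p under 0.05. The small count on all arrays therefore does not by itself show a weak response. In the fit without that array, 1318 was still near the 1111 expected by chance, against 6942 at EC20. The called genes not yet named were the transcripts TC343157, TC350829, EH552414 and TC310806, all higher. Of these, EH552414 was low in the solvent arrays themselves. It had a mean of -3.06 in solvent, -1.22 in water and -1.11 at EC10. All 7 and the 1 were also called in the same direction at EC20, a comparison with the same solvent arrays, so that overlap is partly built in. Of 22140 genes, 4.61% had groups that did not overlap, against 2.86% by chance. Without EC20 replicate A, 17 rose and 12 fell, 7 and 1 of them the same genes, and bbc3 then passed (adjusted p = 0.000656). The count of rises was 4 without EC10 replicate B, EC10 replicate C or solvent replicate D, and g0s2 lost its call without any 1 of the 4 solvent arrays or EC10 replicates B, C or D (adjusted p 0.0613 to 0.131). It also lost it with the replicate letter as a block (adjusted p = 0.0558), with block and array position, without a filter, under quantile scaling, with normexp and in a fit of the compared groups alone. With normexp background correction, which adds an offset of 50 to every corrected signal, 0 genes rose and 0 fell (limma, 23 genes at unadjusted p under 0.05) and cyp19a1b was 0.88 above solvent. With very bright local backgrounds replaced, 246 genes were at unadjusted p under 0.05 (limma). Under median and under quantile scaling cyp19a1b remained called, and f13a1a.1, vtg1 and g0s2 lost their calls. In a fit of the compared groups alone f13a1a.1 lost its call too.

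The comparison of EC20 with solvent control asked the same of 2.4 mg/l. The lists of p53 and apoptosis and of myeloid cells and inflammation rose, and those of retina, neurons and neural progenitors and glia fell. Most measured members of each did not pass, and these 5 calls were lost with an estimated correlation. The interferon-stimulated isg15 (LOC558956 in the files, chromosome 5 at 15652477 to 15652536) rose 48.3-fold (log2 5.59, SE 0.47, n = 4 per group, adjusted p = 5.44e-06), and bbc3 (chromosome 15 at 22403891 to 22403950) rose 9.77-fold (log2 3.29, SE 0.35, adjusted p = 4.45e-05). Both rises were smaller on slide A, which holds EC20 replicate A, with 3.75 for isg15 (others 5.52 to 6.64) and 1.48 for bbc3 (others 3.76 to 3.98). The photoreceptor homeobox gene crx was 5.58-fold lower (log2 -2.48, SE 0.24, adjusted p = 2.06e-05). The growth hormone-releasing hormone gene ghrh rose by 4.07 (SE 0.65). It was above background on 2 of 4 solvent arrays. Against solvent arrays that were all at background, the membrane protein gene ms4a17a.4 was at least 11.1-fold higher, the interferon-induced ifit8 at least 6.74-fold (its difference was smaller without EC20 replicate A), the iodide transporter slc5a5 at least 3.72-fold, the related ms4a17a.1 at least 3.35-fold and the homeobox gene mxtx1 at least 3.22-fold. These bounds include EC20 replicate A, whose background was high (negative controls 129, other EC20 arrays 47.5 to 49.7). They hold only if its values for dim genes are sound, and bounds without it were not computed. The gene prrg3 was higher too, with an SD of 3.02 at EC20, where replicate C was at background, so no fold is given. Further falls were those of the transcription factor bhlhe23 (-2.83), the glucocorticoid receptor co-chaperone fkbp5 (-2.70), the linker histone histh1l1 (-2.66), the cone G protein subunit gnb3a (-2.60, and -3.20 without EC20 replicate A), the glial transcription factor nfia (-2.54), klf11a (-2.39), the retinal adhesion protein rs1a (-2.36) and the linker histone h1-10 (-2.36), with SE from 0.21 to 0.49. The fall of histh1l1 was enlarged by EC20 replicate A, where it lay at 1.52 (other EC20 arrays 3.11 to 3.33).

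Estrogen-responsive genes rose at EC20 as well, 4 of the 7 measured, with 0 falling and 3 not passing (4 adjusted over the list alone). They were vtg1, by 2.64 (SE 0.25), cyp19a1b, by 1.79 (SE 0.20, 3.47-fold, adjusted p = 8.26e-05, n = 3 against 4 because its spot was marked on EC20 replicate A), nots, by 1.71 (SE 0.24), and f13a1a.1 (SE 0.43), whose solvent level was near background. The exact 2-sided permutation p was 0.0286 for each of the 4 genes, again the smallest possible, and cyp19a1b differed by 2.01, 1.89 and 1.37 on the 3 slides with a value. The list had a shift of 1.36 (adjusted p = 1.15e-05), which held with adjusted p = 0.00503 with an estimated correlation. It was the only list called at EC20 for which that was so.

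The p53 and apoptosis list rose, with 11 of 40 measured members up, 0 down and 29 not passing (14 up and 1 down adjusted over the list alone). Besides bbc3 these were led by phlda3 (3.02, SE 0.33), mdm2, the ubiquitin ligase that degrades p53 (2.85, SE 0.35), and gadd45aa, a growth arrest and DNA damage gene (2.68, SE 0.30). The shift was 0.67 (adjusted p = 2.59e-06, and adjusted p = 0.683 with an estimated correlation). Slide A gave -0.29 for this list and the other 3 slides gave 0.76 to 1.06. The myeloid and inflammation list rose by 0.65 (adjusted p = 2.11e-06, and adjusted p = 0.0712 with an estimated correlation), with 9 of 40 members up, 0 down and 31 not passing, and 10 up and 1 down adjusted over the list alone. With isg15 rose the matrix protease mmp9 (2.75, SE 0.24), the protease inhibitor timp2b (2.61, SE 0.26) and socs3a, a suppressor of cytokine signalling (1.99, SE 0.34). Both lists held without EC20 replicate A with an estimated correlation (adjusted p = 0.0292 and 0.0394).

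Of 65 measured neuronal genes 23 fell, 1 rose and 41 did not pass (30 down and 1 up adjusted over the list alone; shift -0.66, adjusted p = 5.32e-09, and adjusted p = 0.174 with an estimated correlation). The neuronal differentiation factors neurod1 (-2.14, SE 0.25) and neurod6b (-2.04, SE 0.26) and the homeobox gene lhx1a (-1.77, SE 0.30) fell, and the neuropeptide gene cart3 rose (2.06, SE 0.29). Of 42 genes of neural progenitors and glia, 16 fell, 2 rose and 24 did not pass (22 and 2 adjusted over the list alone; shift -0.56, adjusted p = 1.15e-05, and adjusted p = 0.683 with an estimated correlation). The myelin gene plp1a (-1.79, SE 0.23), the oligodendrocyte factor olig2 (-1.61, SE 0.30) and pax6b (-1.53, SE 0.29) fell, while cyp19a1b, which is also on this list, rose. Slide A gave -1.61 for the glial list and the others -0.33 to -0.19. Of 38 retinal and photoreceptor genes, 14 fell, 3 rose and 21 did not pass (16 and 6 adjusted over the list alone; shift -0.43, adjusted p = 0.0164, and adjusted p = 0.623 with an estimated correlation). Beside crx, rs1a and neurod1, the bipolar cell homeobox gene vsx1 fell (-2.08, SE 0.24). The retinal call was lost without EC20 replicate C (adjusted p = 0.052).

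**Figure D2:**
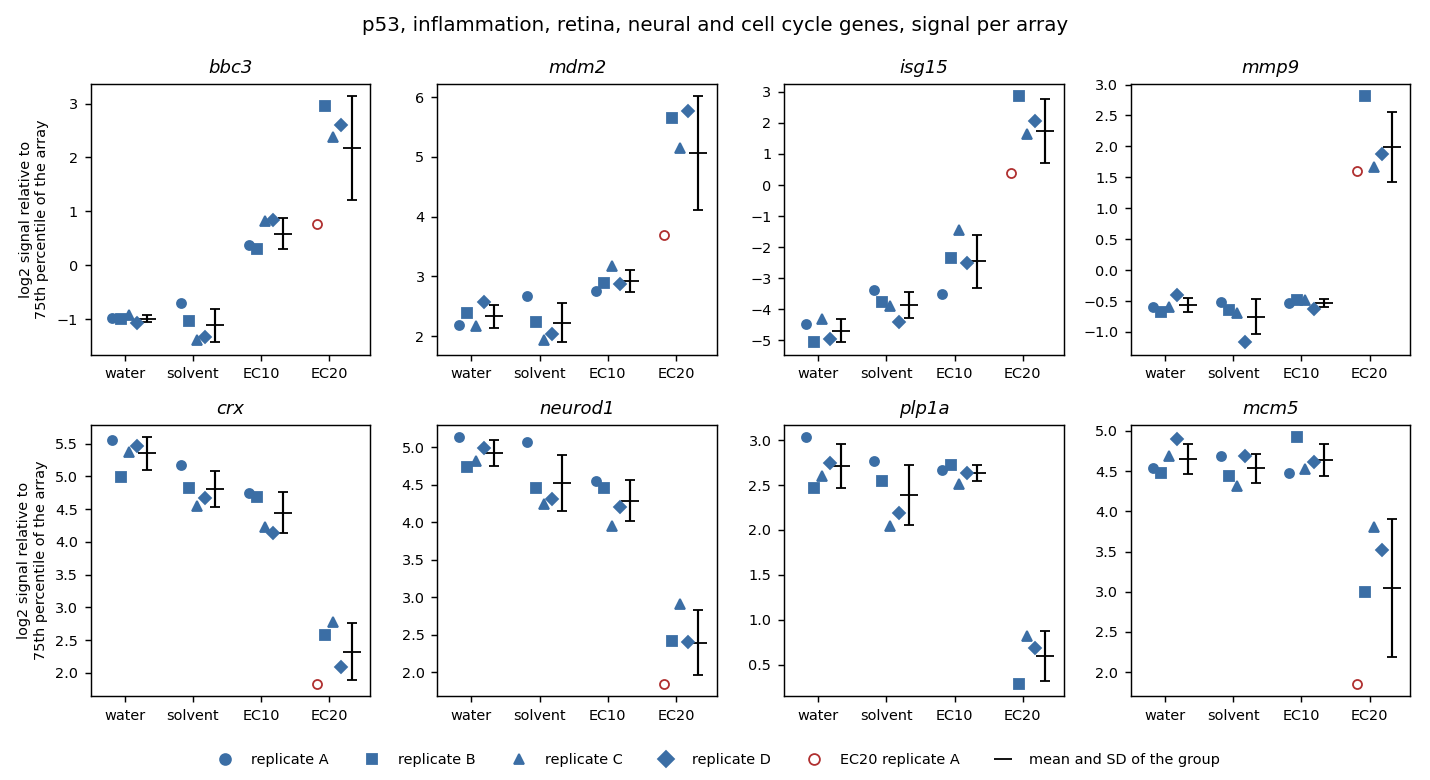
Log2 signal relative to the array's 75th percentile (vertical axis) of bbc3, mdm2, isg15, mmp9, crx, neurod1, plp1a and mcm5 on each array of the 4 groups (horizontal axis); symbols are replicates, the open red circle is EC20 replicate A, and bars are the group mean and SD. At EC20 bbc3 lay 3.29 above solvent and crx 2.48 below it (log2 -2.48).

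In the cell cycle list 5 of 54 genes fell, 0 rose and 49 did not pass (8 and 0 adjusted over the list alone; shift -0.45, adjusted p = 9.25e-05, and adjusted p = 0.895 with an estimated correlation). All 5 were subunits of the replicative helicase: mcm5 (-1.48), mcm2 (-1.46), mcm4 (-1.41), mcm3 (-1.29) and mcm6 (-1.26). Slide A gave -1.69 for the list and the others -0.14 to -0.01, and the call was lost without EC20 replicate A (-0.10, adjusted p = 0.209), where 7 genes fell and 2 rose. Of 77 ribosomal protein genes 0 were called, over all genes or adjusted over the list alone (limma), and the list's shift of -0.39 (adjusted p = 0.00181, and adjusted p = 0.923 with an estimated correlation) turned to 0.08 without EC20 replicate A (adjusted p = 0.284) and to 0.26 under quantile scaling. Its largest members were rpl35a (-0.73, SE 0.43) and rps26 (-0.68, SE 0.36), and slide A gave -1.95.

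The list of cartilage, bone and matrix fell by 0.38 relative to all genes (shift -0.38, adjusted p = 0.00185, and adjusted p = 0.801 with an estimated correlation), with 5 of 51 members down, 1 up and 45 not passing, and 5 and 2 adjusted over the list alone. The hypertrophic cartilage collagen col10a1a fell (-1.96, SE 0.25) and fibronectin fn1b rose (1.78, SE 0.38), and slide A gave -1.06 where the others gave -0.29 to -0.15. The circadian list had 5 of 32 members down, 0 up and 27 not passing (9 and 0 adjusted over the list alone; shift -0.41, adjusted p = 0.0132, and adjusted p = 0.683 with an estimated correlation). The clock repressors nr1d2a (-2.11, SE 0.41) and nfil3-6 (-1.56, SE 0.29) fell. The sterol synthesis list rose (shift 0.31, adjusted p = 0.00855, and adjusted p = 0.683 with an estimated correlation), with -0.20 on slide A and 0.24 to 0.53 on the others, and with 2 of 31 members up, 0 down and 29 not passing, the same adjusted over the list alone. These were pmvk, a mevalonate pathway kinase (1.07, SE 0.30, and 0.68 without EC20 replicate A), and insig1, which restrains sterol synthesis (0.76, SE 0.20). The call of pmvk was lost without any 1 of the solvent arrays (adjusted p 0.0529 to 0.115) and that of insig1 without solvent replicates A, B or C or EC20 replicates B or D (0.0589 to 0.097). The list's call was lost without EC20 replicate B (adjusted p = 0.0621), and 10 members rose and 2 fell without EC20 replicate A.

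The remaining 23 lists were not called at EC20. Those of hormone axes and foreign compounds were steroidogenesis and gonadal axis (1 of 15 up, 0 down, adjusted p = 0.857), thyroid axis (1 of 14 up, 3 down, 0.857), aryl hydrocarbon response (0 of 11 up, 2 down, 0.197), pregnane and phase I xenobiotic response (2 of 16 up, 1 down, 0.077) and conjugation phase II (0 of 26 up or down, 0.668). The androgen receptor ar rose by 1.07 (SE 0.24), and in the thyroid list pax2a fell by 1.38 (SE 0.24) while slc5a5 rose. The stress lists were oxidative stress (1 of 28 up, 0 down, 0.17), heat shock (0 of 31 up or down, 0.965) and unfolded protein and integrated stress response (2 of 39 up, 0 down, 0.668). In the ERK and growth factor list (8 of 41 up, 3 down, 0.17) the immediate early gene fosab rose by 2.83 (SE 0.37). The vascular and blood lists were angiogenesis and endothelium (0 of 50 up, 4 down, 0.105) and erythroid cells (0 of 34 up, 4 down, 0.0616). For muscle they were skeletal muscle (4 of 73 up, 1 down, 0.0698) and cardiac muscle (1 of 31 up, 0 down, 0.0821), and for the lens 1 of 40 up, crygn1 (2.17, SE 0.27), and 1 down, prox1a (-1.61, SE 0.30), with adjusted p = 0.985. Liver (5 of 54 up, 3 down, 0.176) held hepcidin, hamp (1.78, SE 0.28). Then came exocrine and endocrine pancreas (0 of 13 up, 3 down, 0.903), intestine and ionocytes (4 of 41 up, 0 down, 0.435), pigment cells (0 of 35 up, 3 down, 0.572), epidermis and keratin (1 of 49 up, 1 down, 0.529) and hatching gland (0 of 12 up, 2 down, 0.108). The metabolic lists were fatty acid oxidation and PPAR (1 of 51 up, 3 down, 0.506), glycolysis and hypoxia (3 of 49 up, 1 down, 0.175) and oxidative phosphorylation (1 of 68 up, 1 down, 0.176). Of these 23, 12 passed without EC20 replicate A, led by skeletal muscle (shift 0.42, adjusted p = 8.67e-08) and oxidative stress (0.46, adjusted p = 4.42e-06), so that 21 lists were called in all. With all arrays, median and mean change differed in sign for the lists of ERK (-0.01 and 0.21), intestine and ionocytes (-0.11 and 0.13), steroidogenesis (-0.09 and 0.04) and pancreas (0.24 and -0.05).

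**Figure D3:**
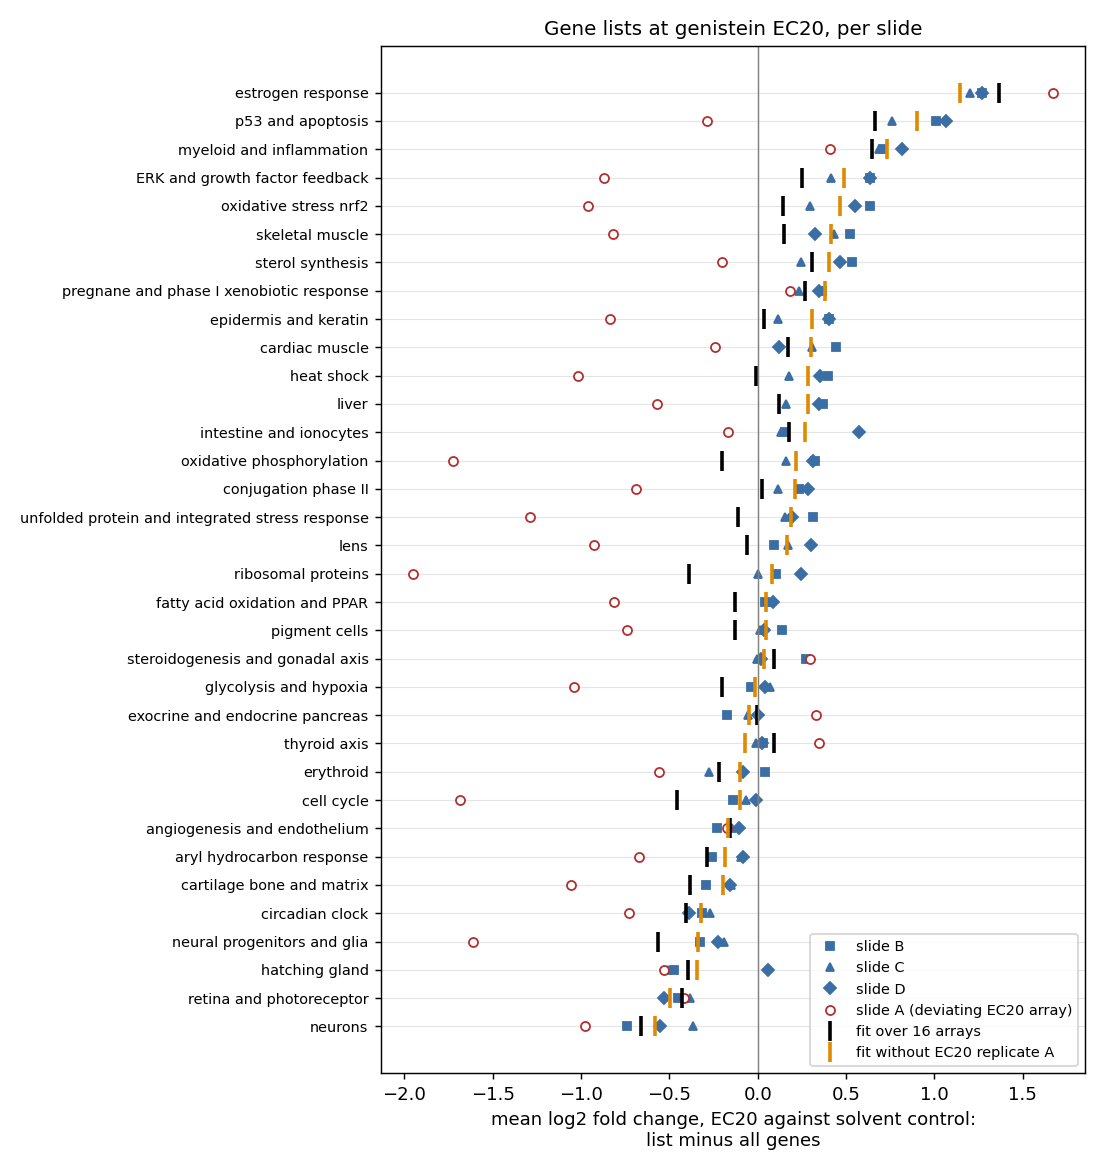
Mean log2 change of each of the 34 lists relative to all genes, EC20 against solvent control (horizontal axis), with a point per slide, slide A as open red circles, a black bar for all 16 arrays and an orange bar without EC20 replicate A. For ribosomal proteins slide A lay at -1.95 and the bars at -0.39 and 0.08.

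Over all genes, limma called 800 higher and 1071 lower at EC20, of which 619 and 771 changed at least 2-fold. On the slides, 594 of 640 higher genes with 4 values and 159 of 160 with 3 values kept their sign on every slide, as did 892 of 904 and 167 of 167 lower genes. Of 18585 genes, 14.6% had groups that did not overlap, against 2.86% by chance. A fit without EC20 replicate A gave 1858 rises and 1855 falls, sharing 768 and 1053 with the first calls. The higher genes numbered 487 without solvent replicate B and 529 without solvent replicate D, and the lower ones 644, 575, 708 and 638 without solvent replicates A, B, C and D. With normexp background correction 4 genes rose and 0 fell (limma, 590 at unadjusted p under 0.05), and 104 of 112 named genes lost their call. A few spots with very bright local backgrounds entered that correction. With these replaced, a fit added after the data were seen, 3923 genes were at unadjusted p under 0.05 (limma). Median scaling moved the median of all genes from -0.11 to -0.51 and left 178 higher and 281 lower genes. Quantile scaling moved that median to -0.31.

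The mean of both doses against solvent control joined the arrays of both concentrations. The estrogen genes rose again, f13a1a.1 by 3.23 (SE 0.37, from a solvent level near background), vtg1 by 2.46 (SE 0.22), cyp19a1b by 2.27 (SE 0.17, 4.82-fold, adjusted p = 7.63e-06, n = 7 against 4) and nots by 1.34 (SE 0.21). Among the p53 genes bbc3 rose by 2.49 (SE 0.30), phlda3 by 1.99 (SE 0.29), mdm2 by 1.77 (SE 0.30) and gadd45aa by 1.65 (SE 0.26). The exonuclease gene exo5 (1.87, SE 0.19) and ms4a17a.5 (1.68, SE 0.24) rose. The sugar transporter slc5a1 was at least 2.71-fold higher, a bound that includes EC20 replicate A with its high background. Falls on all arrays were led by histh1l1 (-1.88, SE 0.29), g0s2 (-1.84, SE 0.28), rs1a (-1.71, SE 0.22), h1-10 (-1.65, SE 0.18), klf11a (-1.64, SE 0.23), arl3l1 (-1.56, SE 0.22), tfap2d (-1.36, SE 0.16) and the photoreceptor and pineal homeobox gene otx5 (-1.34, SE 0.23). The size for histh1l1 was raised by EC20 replicate A, where it lay at 1.52 (other EC20 arrays 3.11 to 3.33).

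Of the 34 lists, 12 were called for the mean of both doses. Estrogen response (4 of 7 up, 0 down, shift 1.35, adjusted p = 3.7e-09) and myeloid and inflammation (3 of 40 up, 0 down, shift 0.41, adjusted p = 1.25e-07) held with an estimated correlation (adjusted p = 1.35e-05 and 0.0334). In the latter isg15 rose by 3.50, mmp9 by 1.48 and timp2b by 1.42, and 4 genes rose adjusted over the list alone. The p53 list rose (8 of 40 up, 0 down, 10 up adjusted over the list alone; shift 0.43, adjusted p = 1.42e-06, and adjusted p = 0.564 with an estimated correlation), with -0.15 on slide A. Neurons (0 of 65 up, 3 down, 14 down and 1 up adjusted over the list alone; shift -0.36, adjusted p = 1.25e-07, and adjusted p = 0.327 with an estimated correlation) and retina (0 of 38 up, 6 down, 10 down and 2 up adjusted over the list alone; shift -0.26, adjusted p = 0.0106, and adjusted p = 0.564 with an estimated correlation) fell, with neurod1 at -1.19 and crx at -1.42. The circadian list fell (0 of 32 up, 1 down; shift -0.27, adjusted p = 0.00805, and adjusted p = 0.564 with an estimated correlation). Neural progenitors and glia (1 of 42 up, 0 down, shift -0.23), cartilage (0 of 51 up, 1 down, -0.20), ribosomal proteins (0 of 77 called, -0.20), cell cycle (0 of 54 called, -0.17) and erythroid cells (0 of 34 called, -0.13) fell and skeletal muscle (0 of 73 called, 0.12) rose as lists, and for these 6 adjusted p = 0.91 with an estimated correlation. Slide A differed from the others for several of these lists. It gave -0.92 for the glial list, where the others gave -0.12 to 0.031, -0.87 for cell cycle (others -0.0079 to 0.086), -1.11 for ribosomal proteins (others 0.0076 to 0.17), -0.57 for cartilage (others -0.12 to -0.093) and -0.39 for skeletal muscle (others 0.19 to 0.34). The calls of the glial and retinal lists were lost without solvent replicate A (adjusted p = 0.0533), that of cartilage without EC20 replicate A (0.109), that of ribosomal proteins without it (0.674), solvent replicate A (0.0552) or EC10 replicate A (0.0535), that of cell cycle without any 1 of these 3 (0.866, 0.0894 and 0.0555) or EC10 replicate C (0.0583), that of erythroid cells without EC20 replicates A or C, EC10 replicates A, C or D or solvent replicates A, B or C (0.0512 to 0.103), and that of skeletal muscle without EC20 replicates B, C or D, EC10 replicates A or B or solvent replicates A, C or D (0.0502 to 0.306). Without solvent replicate A 6 lists were called, and 19 without EC20 replicate A.

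Over all genes, 176 were higher and 117 lower for the mean of both doses, and 131 of 132 and 94 of 94 with values on 4 slides kept their sign on each. Of 18550 genes, 1.36% had groups that did not overlap, against 0.404% by chance. Without EC20 replicate A 632 rose and 571 fell, including all 176 and 117. The higher genes numbered 109, 83, 80 and 74 without solvent replicates A, B, C and D and 115 without EC10 replicate C. The lower ones numbered 54, 40, 48 and 42 without solvent replicates A to D, 63 without EC10 replicate C, 64 without EC10 replicate D and 76 without EC20 replicate D. Under quantile scaling 129 were higher and 138 lower. With normexp background correction 0 rose and 0 fell (limma, 190 genes at unadjusted p under 0.05, and 1705 with bright local backgrounds replaced).

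The comparison of EC20 with EC10 tested the difference between the doses itself. The induction of cyp19a1b was smaller at EC20, by -0.95 (SE 0.20, adjusted p = 0.0143, n = 3 against 4), with -0.94, -1.09 and -1.05 on the 3 slides with a value and an exact 2-sided permutation p of 0.0286, the smallest possible (0.1 after adjustment over the list's 7 genes). The other estrogen genes did not differ past the threshold, with vtg1 at 0.35 (SE 0.25), nots at 0.74 (SE 0.24) and f13a1a.1 at -0.47 (SE 0.43). Higher at EC20 than at EC10 were isg15 (4.19, SE 0.47), ms4a17a.4 (4.19, SE 0.32), ifit8 (at least 7.43-fold), tmem176l.2 (at least 6.48-fold) and the growth factor fgf2 (at least 4.67-fold). The size for ms4a17a.4 is not well measured, since it was above background on 1 of 4 EC10 arrays. The differences of ifit8 and fgf2 were smaller without EC20 replicate A. The bounds of ifit8, tmem176l.2 and fgf2 include that array, whose background was high, so they are not safe lower limits. Lower were bhlhe23 (-2.57, SE 0.31), fkbp5 (-2.22, SE 0.46), the retinal homeobox gene six7 (-2.13, SE 0.29), crx (-2.12, SE 0.24), nfia (-2.11, SE 0.31), plp1a (-2.03, SE 0.23), vsx1 (-2.01, SE 0.24), the Notch target her4.5 (-1.96, SE 0.34), sp5l (-1.94, SE 0.24) and neurod1 (-1.90, SE 0.25). The call of cyp19a1b was lost without EC20 replicate D (-0.85, adjusted p = 0.0552) and under median scaling. It was also lost with trend and robust variances, with block and array position as terms, in a fit of the compared groups alone and with normexp, plain or with capped backgrounds.

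Of the 34 lists, 12 were called between the doses and 0 of them with an estimated correlation (limma). Lower at EC20 were neurons (17 of 65 down, 1 up; 34 down and 1 up adjusted over the list alone; shift -0.60, adjusted p = 3.74e-09, and adjusted p = 0.449 with an estimated correlation), neural progenitors and glia (14 of 42 down, 1 up; 24 and 1 adjusted over the list alone; -0.67, adjusted p = 1.32e-08, and adjusted p = 0.58 with an estimated correlation), retina (11 of 38 down, 2 up; 11 and 3 adjusted over the list alone; -0.34, adjusted p = 0.0236, and adjusted p = 0.58 with an estimated correlation) and cell cycle (7 of 54 down, 0 up; 11 and 1 adjusted over the list alone; -0.56, adjusted p = 7.16e-08, and adjusted p = 0.761 with an estimated correlation), where mcm5 differed by -1.59 and mcm2 by -1.55. Higher were p53 and apoptosis (10 of 40 up, 0 down; 14 and 0 adjusted over the list alone; 0.47, adjusted p = 1.32e-05, and adjusted p = 0.712 with an estimated correlation), with mdm2 at 2.15, phlda3 at 2.06 and gadd45aa at 2.06, and myeloid and inflammation (7 of 40 up, 0 down; 10 up and 3 down adjusted over the list alone; 0.48, adjusted p = 0.000282, and adjusted p = 0.449 with an estimated correlation), with socs3a at 2.61, mmp9 at 2.52 and timp2b at 2.39. The ERK list was higher (9 of 41 up, 1 down; 0.36, adjusted p = 0.00788, and adjusted p = 0.904 with an estimated correlation), with fosab at 2.43 and junba at 1.59. Sterol synthesis (0.31), cardiac muscle (0.21), cartilage (-0.36), hatching gland (-0.54) and ribosomal proteins (-0.37) made up the 12, with adjusted p = 0.58, 0.748, 0.761, 0.58 and 0.963 with an estimated correlation. Slide A gave -0.28 for the p53 list, -0.56 for the ERK list, -0.18 for cardiac muscle and -0.0053 for sterol synthesis, where each other slide was above 0. For ribosomal proteins it gave -1.67 and the others -0.017 to 0.15. For cell cycle it gave -1.62 (others -0.40 to -0.11), for the glial list -1.38 (others -0.46 to -0.42) and for cartilage -0.98 (others -0.40 to -0.070). Calls were lost for the ERK list without EC20 replicate B (adjusted p = 0.135) or D (0.0856), for retina without EC20 replicates B (0.0623), C (0.0745) or D (0.0833) or EC10 replicate B (0.181), for hatching gland without EC20 replicate C (0.106), for cardiac muscle without EC10 replicate A (0.0626) or EC20 replicates B, C or D (0.275, 0.0745 and 0.093), and for ribosomal proteins without EC20 replicate A, where the shift was 0.10 and 20 lists were called.

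Over all genes, 494 were higher and 590 lower at EC20 than at EC10, of which 428 and 523 were also called in the same direction against solvent. Both comparisons use the EC20 arrays, so that overlap is partly built in. On the slides 382 of 394 and 501 of 506 genes with 4 values kept their sign on each. Of 18584 genes, 11.9% had groups that did not overlap, against 2.86% by chance. Without EC20 replicate A 1087 were higher and 1048 lower, sharing 468 and 578. The counts were 225 and 214 without EC10 replicate A, 299 and 313 without EC10 replicate C, and 265 and 290 without EC10 replicate D. With normexp background correction 0 were higher and 0 lower (limma, 267 genes at unadjusted p under 0.05, and 3722 with bright local backgrounds replaced).

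Across genes, the changes at EC10 and EC20 against the same solvent arrays had a Pearson correlation of 0.408 and a covariance of 0.0816. Simulated unchanged groups sharing those arrays gave 0.494 and 0.0644 on average over 50 draws. The simulation gave all arrays the same spread for a gene, estimated with EC20 replicate A included, so the noise of the solvent arrays may be overstated. With the solvent arrays split so that the doses shared none, the correlation was 0.0902 to 0.238 over the 6 splits. Without EC20 replicate A the correlation was 0.516 against a simulated 0.462, and 0.219 to 0.336 with split solvent arrays. The covariance was then 0.0965 against a simulated 0.0336. Genes are not independent replicates, so no p is given. At the level of single genes, f13a1a.1, cyp19a1b, vtg1 and g0s2 changed in the same direction at both doses.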

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

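The tests of a sound array with another pool, of the share of calls kept without EC20 replicate A, of a delay of the whole embryo and of the smaller cyp19a1b response were chosen only after their results were seen. In groups of 4 arrays, a value was listed when its gap to the nearest other array took up most of the group's range, which chance gives in about 1 of 20 groups. Of 767 groups 70 did so, where 38.35 are expected by chance, and 25 of the 70 were on EC20 replicate A.

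EC20 replicate A stood far from the other EC20 arrays in its 75th percentile (1099, others 193 to 303), its non-uniform spots (18.6%, others at most 0.0868%) and its negative controls, with a median raw signal of 129 (others 47.5 to 49.7). Its negative controls, which match no zebrafish transcript, were 2.56 times the highest of the other 15 arrays, which argues against a different embryo pool on a sound array. The 10 viral E1A control probes deviated 8.46 times as much as on the array with the next largest deviation, and 98.1% of their spots were well above background against 1.56% to 12.5% elsewhere. A fault of the array or its hybridization is a candidate explanation. On the other arrays the E1A probes lay mostly at background, as negative controls do. Their rise here thus repeats the raised background of this array and is not separate support. A fault in labelling its RNA stays open, and of biological explanations only the different pool was tested.

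At EC20 the neural and retinal lists fell while the p53 and inflammation lists rose, though on all 16 arrays these calls were lost with an estimated correlation. All 71 members of the 5 lists that were called in their list's direction kept that call without EC20 replicate A (100%). With slide and array position as terms, 71 kept their direction and most of their change (100%). Groups were spread over the positions (EC20 at 4, 1, 2 and 2, solvent at 2, 3, 4 and 1 on slides A to D). A position term could thus take up only part of a difference, so its result says little about position. Slides B to D, without that array, gave 0.76 to 1.06 for p53 and 0.69 to 0.81 for inflammation. They gave -0.74 to -0.36 for neurons, -0.33 to -0.19 for glia and -0.53 to -0.39 for retina. These values argue against that array as the whole cause. Called members that went against their list, such as cart3 and cyp19a1b, were not counted. Of all genes called at EC20, 768 of 800 higher and 1053 of 1071 lower ones also kept their call without that array, so this is not particular to these lists. Above the mean of all genes by more than their spread between slides lay 0 of the lists of skeletal muscle, cardiac muscle, lens and liver with all arrays, where EC20 replicate A widens the spread, and 4 on the other 15 arrays. On those 15 arrays the shifts were 0.42 (SD 0.10 between slides), 0.30 (SD 0.16), 0.17 (SD 0.11) and 0.29 (SD 0.11), which argues against a delay of the whole embryo alike in all tissues, though with all 16 arrays this cannot be told apart. The lists of cartilage (-0.29 to -0.15 on slides B to D) and of angiogenesis and endothelium (-0.23 to -0.11) lay below the mean of all genes, so a delay of some tissues stays open. An effect of 2.4 mg/l genistein on nervous tissue may remain, as a hypothesis found on these same arrays and not itself tested. No test set nervous tissue apart from other lists called at EC20, such as circadian clock and sterol synthesis.

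The gene cyp19a1b was induced less at EC20 than at EC10. Its difference of -0.95 lay at percentile 41.5 of the 41 other genes of the neural progenitor and glia list (median -0.91, quartiles -1.14 to -0.30). These genes include values of EC20 replicate A, on which cyp19a1b has none. On the other 15 arrays it lay at percentile 14.6 (median -0.57, quartiles -0.80 to -0.012), outside the middle of the list, so fewer or less mature neural cells cannot be told apart from other causes. A weaker estrogen response of the whole embryo cannot be told apart either. The other estrogen genes called at EC20 had a median difference of 0.35, with nots (0.74) and vtg1 (0.35) above that of cyp19a1b by over 2 SE and f13a1a.1 (-0.47, SE 0.43) not.

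The real split called the most genes at EC10 (8 genes, highest other split 0, and 1 of 35 splits as large) and at EC20 (1871, highest other 165, 1 of 35). The same held for the mean of both doses (293, highest other 107, 1 of 100) and between the doses (1084, highest other 229, 1 of 35). A share of 1 of 35 is the smallest that 35 splits can give, and it was not adjusted over the comparisons. Other splits mix treated and control arrays, which widens the spread within their groups. These shares therefore do not exclude chance. For solvent against water the count of 0 (highest other 0, 35 of 35) is matched by any split, so it tells nothing about chance. For the numbers of lists called, the splits neither exclude chance nor show it, since some other splits also part most treated from most control arrays. At EC20 the highest other split set EC20 replicate A with solvent replicates A, B and C, apart from EC20 replicates B, C and D. The real splits gave 1, 8, 11, 12 and 12 lists in the order of the report and the highest other splits 6, 16, 20, 20 and 21, with 23 of 35, 6 of 35, 22 of 35, 39 of 100 and 15 of 35 splits as large.

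On EC20 replicate A the following log2 values, relative to the array's 75th percentile, were far from the other EC20 arrays. Higher were tdo2b (-1.39), ghrh (-0.23), lepb (-0.90), alpi.2 (-1.63), pmvk (-0.70), gfi1aa (-0.46) and the mean of the thyroid list (-1.30). Lower were histh1l1 (1.52), pax2a (0.27), tal1 (-1.02), slc4a1a (1.74), hbbe2 (3.73), foxi1 (-1.66), angptl4 (0.46), rplp2b (5.57) and rpl10a (3.38). Also lower were the means of the lists of pregnane and phase I response (-2.04), cell cycle (0.54), neural progenitors and glia (1.04), pigment cells (0.10), fatty acid oxidation (0.41) and ribosomal proteins (4.75).

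In the same unit, EC20 replicate B was higher for hspa8b (-0.73) and ms4a17a.4 (-0.73) and had a replicate probe CV of 13.2%, and EC20 replicate C was lower for rs1a (-3.42). EC10 replicate A stood apart for g0s2 (-1.05), ms4a17a.1 (-5.86), gadd45aa (-0.76), tcap (3.18) and the hatching gland list (0.33). EC10 replicate B did so for dnajb9b (-3.58), tal1 (1.76), pax6b (0.98), alpi.2 (-4.75), adma (-3.05), nr1d2a (1.43) and zbtb20 (-0.22). EC10 replicate C did so for socs3a (0.092) and otx5 (2.20), and EC10 replicate D for hbba2 (-2.18) and six7 (2.22).

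Among the solvent arrays, replicate A stood apart for ly6pge (0.23), pax6b (2.703), vsx1 (2.12), crygn1 (-2.37), nr1d2a (0.37), bcl3 (-5.49), her4.5 (0.71) and the lists of thyroid axis (-1.48) and pigment cells (0.92). Solvent replicate C had a 75th percentile of 205, and solvent replicate D stood apart for hbba2 (-4.04) and htra3a (-2.09). Among the water arrays, replicate A stood apart for cysltr2b (-3.77), hist1h2a2 (-5.36) and ndrg1b (2.01), replicate B for otx5 (2.79) and the cartilage list (1.70), and replicate C for dnajb9b (-3.26) and lepb (-1.58). Water replicate D stood apart for egr1 (2.32), cyp2k16 (-1.36), mcm2 (5.52), timp2b (-1.93), dla (1.73) and the pancreas list (-1.28).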

How the results depend on the processing

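The fits without EC20 replicate A in every comparison, with array weights and with a capped local background were chosen only after the data were seen. Unless a cause is given, the cause of a change was not tested. Values for counts are genes higher and lower, and values for lists are shifts. Signal over background limits the size of the folds, since for genes near background a fold shrinks with any offset and a fall ends at the background. Each comparison rests on 4 arrays per group, and where an array is left out its group has 3. Of 112 genes named for EC20, 112 gave the same result with the values of the series table, 84 without a filter and 80 under quantile scaling. Under median scaling 43 did so, and 5 with normexp. The same result means a kept call or, for list members named without a call, a move of less than their SE. Of 2886 checks of these genes 2329 gave the same result, 540 a lost call, 11 another size and 6 the other direction. For lists at EC20 it was 269 of 297, and for genes at EC10, for the mean and between the doses 401 of 479, 1297 of 1635 and 1499 of 1948. The median change of all genes at EC20 was -0.11, -0.31 under quantile and -0.51 under median scaling, so that falls and rises there are relative to it. The rise of cyp19a1b at both doses kept its direction under every setting run, and lost its call only with normexp, plain or with capped backgrounds, on all 16 arrays.

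Normexp with an offset of 50 called 0 and 0 genes at EC10, 4 and 0 at EC20, 0 and 0 for the mean of both doses and 0 and 0 between the doses (limma, 23, 590, 190 and 267 at unadjusted p under 0.05). It called 12 lists for solvent against water and 16 at EC10. Up to 21 spots per array with very bright local backgrounds entered its background fit, and replacing them gave back part of the calls. It gave cyp19a1b 0.88 at EC10, 0.48 at EC20, 0.68 for the mean and -0.40 between the doses. Directions that reversed with it were, at EC20, parp6a (0.11), trpv6 (-0.0019) and hce2l2 (0.22), for the mean slc16a6b (0.22), cyp2r1 (0.061) and the skeletal muscle list (-0.059). Between the doses they were htra3a (-0.12), slc5a5 (-0.22), ms4a17a.1 (-0.43), bcl3 (-0.053), hist1h2a2 (-0.073), cyp3a65 (-0.30), cyp2k16 (-0.023), fosl1a (-0.056), apobec2b (-0.18) and the lists of cartilage (0.040) and ribosomal proteins (0.16). These are fitted differences and not bounds, also for genes at background in a group, whose direction is then not well measured. The glia list was 0.072 for solvent against water, and at EC10 p53 was -0.050 and liver -0.10. With bright backgrounds replaced by the array's median, EC10 gave 0 and 0 genes (limma, 246 at unadjusted p under 0.05) and cyp19a1b 0.93, EC20 229 and 817 and cyp19a1b 0.48, the mean 42 and 68, and the doses 156 and 482 with cyp19a1b at -0.45. The same without EC20 replicate A gave 6 lower genes and 14 lists at EC10, 23 lists at EC20, 306 and 264 genes and 19 lists for the mean, and 19 lists and cyp19a1b at -0.45 between the doses. There ribosomal proteins reversed to 0.037, 0.032 and 0.0096 at EC20, for the mean and between the doses, and cell cycle to 0.0052 for the mean.

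Quantile scaling gave 1 and 0 genes at EC10 (limma, 502 at unadjusted p under 0.05) and 18 lists at EC20, and reversed taldo1 (-0.027), trpv6 (-0.20) and fa2h (-0.26) at EC20 and ribosomal proteins at EC20 (0.26), for the mean (0.13) and between the doses (0.27). Median scaling gave 0 lists for solvent against water, 2 higher genes and 2 lists at EC10, 178 and 281 genes at EC20, 21 and 10 for the mean, and 78 and 106 with cyp19a1b at -0.95 between the doses. The series table gave 2 lower genes at EC10. Without a filter 2 lists were called for solvent against water, 4 and 0 genes at EC10 (limma, 501 at unadjusted p under 0.05), 530 and 567 genes and 18 lists at EC20, 72 and 42 genes for the mean and 272 and 241 between the doses, with 35971 genes to adjust over instead of 22217. Genes above background on all 16 arrays gave 1 and 1 for solvent against water, 1 and 2 at EC10 and 112 and 119 for the mean.

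The replicate letter stood for a shared slide, and whether it also stands for a spawn was not given. Of 21 pairs of groups on the same slide, 6 had correlated deviations above 0.1 (-0.519 to 0.269), 3 of them EC10 with solvent control (0.161 to 0.269). With the replicate as a block 0 genes were lower at EC10 (limma, 431 at unadjusted p under 0.05), 600 and 701 called at EC20, 88 and 49 for the mean and 312 and 307 between the doses. The block ended the calls of 20 of 112 genes named for EC20, 15 of 55 for the mean and 20 of 82 between the doses. With block and array position 5 lists were called for solvent against water, 4 and 0 genes at EC10 (limma, 508 at unadjusted p under 0.05), 596 and 665 at EC20, 63 and 24 for the mean, and 341 and 373 with cyp19a1b at -1.08 between the doses. Of the 12 list calls each, 1 was lost for the mean and 3 between the doses. Fits of the compared groups alone, with fewer arrays for the spread, gave 2 and 2 genes for solvent against water, 3 lower at EC10, 200 and 157 at EC20, 86 and 41 for the mean, and 66 and 35 with cyp19a1b at -0.95 between the doses. With every probe tested on its own 0 lists were called for solvent against water and 18 at EC20. With trend and robust variances solvent against water gave 1 and 1, EC10 3 lower, and cyp19a1b lost its call between the doses (-0.95). Against the water control EC10 gave 9 lower genes and 2 lists, EC20 1573 and 2424, and the mean 704 and 1097. Against the mean of both controls they were 10 lower and 4 lists, 1612 and 2414, and 685 and 1006. With an estimated correlation the lists called were 0, 1, 1, 2 and 0 in the order of the report.

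The fit without EC20 replicate A reversed ribosomal proteins at EC20 (0.082), for the mean (0.034) and between the doses (0.10), and cell cycle for the mean (0.0036). With the replicate block as well, 2 genes were lower for solvent against water, 16 and 10 called at EC10, 1752 and 1604 with 22 lists at EC20, 539 and 413 with 19 lists for the mean, and 1074 and 923 with 20 lists between the doses. There ribosomal proteins were 0.11, 0.048 and 0.12, and cell cycle 0.0097 for the mean. Array weights, in which EC20 replicate A had 0.0316, gave 2694 and 3433 genes and 2 lists for solvent against water, 134 and 93 with 14 lists at EC10, 3017 and 3159 with 20 lists at EC20, 1607 and 1543 for the mean, and 2025 and 2399 with 19 lists between the doses. With them cell cycle for the mean was 0.0051 and ribosomal proteins between the doses 0.030. The weights were estimated from these same arrays, so the counts may be too high.

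Leaving out each array in turn gave, for solvent against water, 0 to 1 higher, 0 to 2 lower and 0 to 2 lists. At EC10 it gave 4 to 17 higher, 0 to 12 lower, cyp19a1b 2.67 to 2.82 and 3 to 12 lists. At EC20 it gave 487 to 1858 higher, 575 to 1855 lower, cyp19a1b 1.68 to 1.90 and 10 to 21 lists. For the mean it gave 74 to 632 higher, 40 to 571 lower, cyp19a1b 2.21 to 2.34 and 6 to 19 lists. Ribosomal proteins ranged from -0.59 to 0.082 at EC20, from -0.30 to 0.034 for the mean and from -0.58 to 0.10 between the doses, and cell cycle from -0.24 to 0.0036 for the mean. Between the doses it gave 225 to 1087 higher, 214 to 1048 lower, cyp19a1b -1.07 to -0.85 and 10 to 20 lists. The correlation of the doses was 0.332 to 0.516 and their covariance 0.0729 to 0.0999. With the solvent arrays split it was 0.237, 0.231, 0.238, 0.227, 0.222 and 0.0902 with A and B, A and C, A and D, B and C, B and D, and C and D for EC10, with covariances of 0.0506, 0.0528 and 0.0243 in the last 3. Without EC20 replicate A and with water as the reference of EC10 it was 0.239.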

Other observations

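No test was chosen for this part; the genes below were picked only after their values were seen, and other scalings were not looked up for them.

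Single genes also changed at EC20 beside those of the report. Among apoptosis genes, casp8 (2.39, SE 0.35) and gadd45bb (2.11, SE 0.23) rose. Of the list of intestine and ionocytes, stc1 (2.58, SE 0.28) and foxi1 (1.62, SE 0.34) rose. The neuropeptide gene oxt (-1.66, SE 0.24), the neural crest factor tfap2e (-1.65, SE 0.28) and the keratin gene krt1-c5 (-1.76, SE 0.24) fell. All 7 kept their call and direction without EC20 replicate A.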
